A study of Mus musculus with 26 samples.

How the data were processed

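The data are RNA-seq of polyA RNA from mouse (C57BL/6J) oocytes and preimplantation embryos. Per the labels, females carrying the Zp3-Cre transgene, which is active in growing oocytes, and conditional alleles of Kdm3a and Kdm3b gave oocytes that lack both H3K9 demethylases. Those oocytes were fertilised in vitro with wild-type sperm, and the resulting maternal double-knockout embryos are called mDKO here. The 26 libraries form 13 groups of 2, each library made from a pool of 12 to 20 embryos. One table holds control and mDKO MII oocytes, early 2-cell embryos (E2C) and late 2-cell embryos (L2C) without injection. A further table holds 4 injected E2C groups: control embryos with mCherry, and mDKO embryos with mCherry, Kdm3aWT or Kdm3aHA. The last table holds wild-type 4-cell embryos (4C) injected with mCherry, Kdm3aWT or Kdm3aHA. The meaning of HA is not given in the sources used here, so the construct is named as the labels name it.

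Per the labels' protocols, MII libraries were made with TruSeq Stranded mRNA, and E2C and 4C libraries with SMART-Seq v4 or SMART-Seq mRNA LP. Which kit each E2C or 4C library had, the kit of the L2C libraries, and which of the Illumina sequencers named there read each library are not given in the sources used here. The values are TPM, which share out a fixed total among transcripts after correction for their length, 1 column per library, as deposited by the authors. The submitters' processing notes name STAR 2.7.10b, Bowtie2 2.3.4.1, RSEM 1.3.1, SAMtools 1.9 and the build mm10, without saying which step each served. Annotation, filters and strand settings are not given in the sources used here. Each table lists the same 24412 gene symbols, and library totals run from 999986 to 1000000 TPM. Because every library sums to about the same total, TPM keeps no sequencing depth, so the depth is unknown and no counting interval is given. A gene that takes a larger share lowers the TPM of all others.

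Of these symbols, 24289 matched NCBI RefSeq for GRCm38.p6 (the assembly that mm10 represents), which gave the coordinates, and 24045 matched GENCODE M21 transcripts, which gave length and GC content. All 26 columns matched 1 sample each by name, and the number of columns of unmatched samples left out was 0.

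Tests used limma 3.58.1 in R 4.3.3 on log2(TPM + 1): linear models (lmFit), empirical Bayes moderation with a mean-dependent trend (eBayes), two-sided p-values and Benjamini-Hochberg adjustment over the genes tested, with calls at an adjusted p under 0.05. Genes with a TPM of at least 1 in at least 2 libraries of the fit were tested. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM. Each mDKO against control comparison without injection used the 4 libraries of its stage. The 8 injected E2C libraries shared 1 fit, as did the 6 injected 4C libraries. The difference of the mDKO effect between L2C and E2C was an interaction contrast over the 12 libraries without injection. With 2 libraries per group no exact permutation test can reach the threshold, the smallest p of 2 against 2 being 0.333, and no group was large enough for an outlier test. The labels do not say whether the pools of a group came from separate matings or days, so p-values may measure only technical spread between pools.

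Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternative settings. They were the targeted and paralogous demethylases, H3K9 methylation machinery, early 2-cell (minor activation) genes, the Obox homeobox family, regulators of genome activation, ribosome biogenesis, cytosolic ribosomal proteins, proteasome, RNA polymerase II and spliceosome, oocyte and maternal-effect genes, maternal mRNA clearance, pluripotency and early lineage factors, germline genes repressed by G9a or DNA methylation, imprinted genes, p53 targets, interferon response, heat shock and unfolded protein response, and cell cycle. Lists for RNA from other sources were cumulus and granulosa cell markers, sperm and spermatid markers, blood cell markers and mitochondrially encoded transcripts. Lists with at least 5 tested members were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation. They were also tested with fry, which asks whether members move on balance in 1 direction. These p-values were adjusted over the lists within a comparison, and unless another test is named, a list's adjusted p is that of camera at the preset correlation.

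Derived sets were the E2C-lower (663) and E2C-higher (273) genes, called without injection with a log2 fold change of at least 1 in size and tested in the injected embryos. Stage sets came from control embryos alone. The minor-activation set (607 genes) rose from MII to E2C by a log2 fold change of at least 2 from a mean TPM under 1, and the major-activation set (679) did so from E2C to L2C. The maternal-decay set (2327) had a log2 fold change of -2 or lower from MII to L2C and a mean TPM of at least 10 at MII. Each of these changes had an adjusted p under 0.05. MII libraries had another kit than E2C libraries, and whether E2C and L2C libraries differed in kit is not given in the sources used here, so the stage sets are descriptive, and each was tested only where it shared no libraries with its definition.

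Named genes followed 1 rule. Kdm3a, Kdm3b and Jmjd1c came first. Then came the 10 highest and 10 lowest log2 fold changes among called genes with a mean TPM of at least 5 and both libraries of one group above both of the other, leaving out predicted-gene and clone names. From each list came up to 4 called members with the largest change, or up to 2 of the highest mean TPM where none was called. Where fewer than 5 genes were called in a direction, the 5 smallest unadjusted p-values were named as not passing. A subset is printed, in that order.

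Alternatives were a pseudocount of 0.1, no filter on low TPM, median-ratio size-factor scaling, the replicate number as a block, other libraries in the fit, and leaving out each library in turn. In the last case the lone library of a group is assumed to vary like the other groups. After the data were seen, 4 alternatives were added: the mDKO Kdm3aHA or the control mCherry libraries in place of the mDKO mCherry libraries, and the gene lists without each library in turn and with other libraries in the fit. The scripts were tested on simulated data with known changes before they were used. Simulated changes of log2 1 and 2 were recovered in 83% and 100% of 100 genes each in the MII fit, and in 89% and 100% for E2C. In the 4C fit of Kdm3aWT against mCherry only 7% and 60% were recovered, and for the stage difference 42% and 97%. Unchanged genes made up 2.90% to 9.77% of the calls in the simulated contrasts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15 and NumPy 2.4.6.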

Results

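RNA was profiled in 26 libraries of pooled mouse oocytes or embryos, in 13 groups of 2. Control and mDKO embryos, which lack maternal KDM3A and KDM3B, were sampled at MII, E2C and L2C. Injected embryos added 4 groups at E2C and 3 at 4C. Because each library is given as TPM, its read depth is unknown. Between 7649 and 12396 genes reached a TPM of 1 per library, and the correlation across genes between the replicates of a group lay between 0.945 and 0.991. Values after ± are standard errors for log2 fold changes and SDs for TPM, with n = 2 libraries per group throughout. Coordinates are on mm10.

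Kdm3a (chromosome 6, 71588970 to 71632990) and Kdm3b (chromosome 18, 34777008 to 34839370) encode the demethylases of mono- and dimethylated H3K9 that were targeted. In control MII oocytes Kdm3a stood at 8.08 and 8.83 TPM in replicates 1 and 2, and in mDKO oocytes at 0.725 and 0.718. Kdm3b stood at 26.6 and 24.97 TPM in control and at 1.75 and 1.87 in mDKO oocytes. At E2C the Kdm3a values were 2.59 and 2.07 in control and 0.642 and 0.557 in mDKO embryos, and those of Kdm3b were 1.05 and 0.400 against 0.129 and 0.289. At L2C, after the embryonic genome is switched on, Kdm3a reached 34.1 and 43.8 TPM in control and 28.4 and 26.3 in mDKO embryos. Kdm3b was then at 3.06 and 3.70 TPM in control and at 0.651 and 1.79 in mDKO embryos. Among injected E2C embryos, Kdm3a was at 2.12 and 1.81 TPM in control mCherry and at 0.262 and 0.411 in mDKO mCherry. It reached 4122 and 2315 TPM with Kdm3aWT and 4043 and 3907 with Kdm3aHA, a level that includes the injected RNA. Kdm3b in these embryos was at 0.710 and 0.722 TPM in control and between 0.128 and 0.254 in the 6 mDKO libraries. In 4C embryos Kdm3a was at 21.8 and 6.24 TPM with mCherry, 108 and 53.4 with Kdm3aWT, and 70.5 and 161 with Kdm3aHA, and Kdm3b was between 2.31 and 5.25 TPM. At MII and E2C both targeted genes lay on the side that the labels give. At L2C Kdm3a lay nearer to control and the lower Kdm3b did not hold without single libraries, so that these genes do not settle the label there. The L2C titles say DKO where their genotype label says maternal double knockout, as at the other stages. Which part of each gene the conditional alleles remove is not given in the sources used here.

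**Figure D1:**
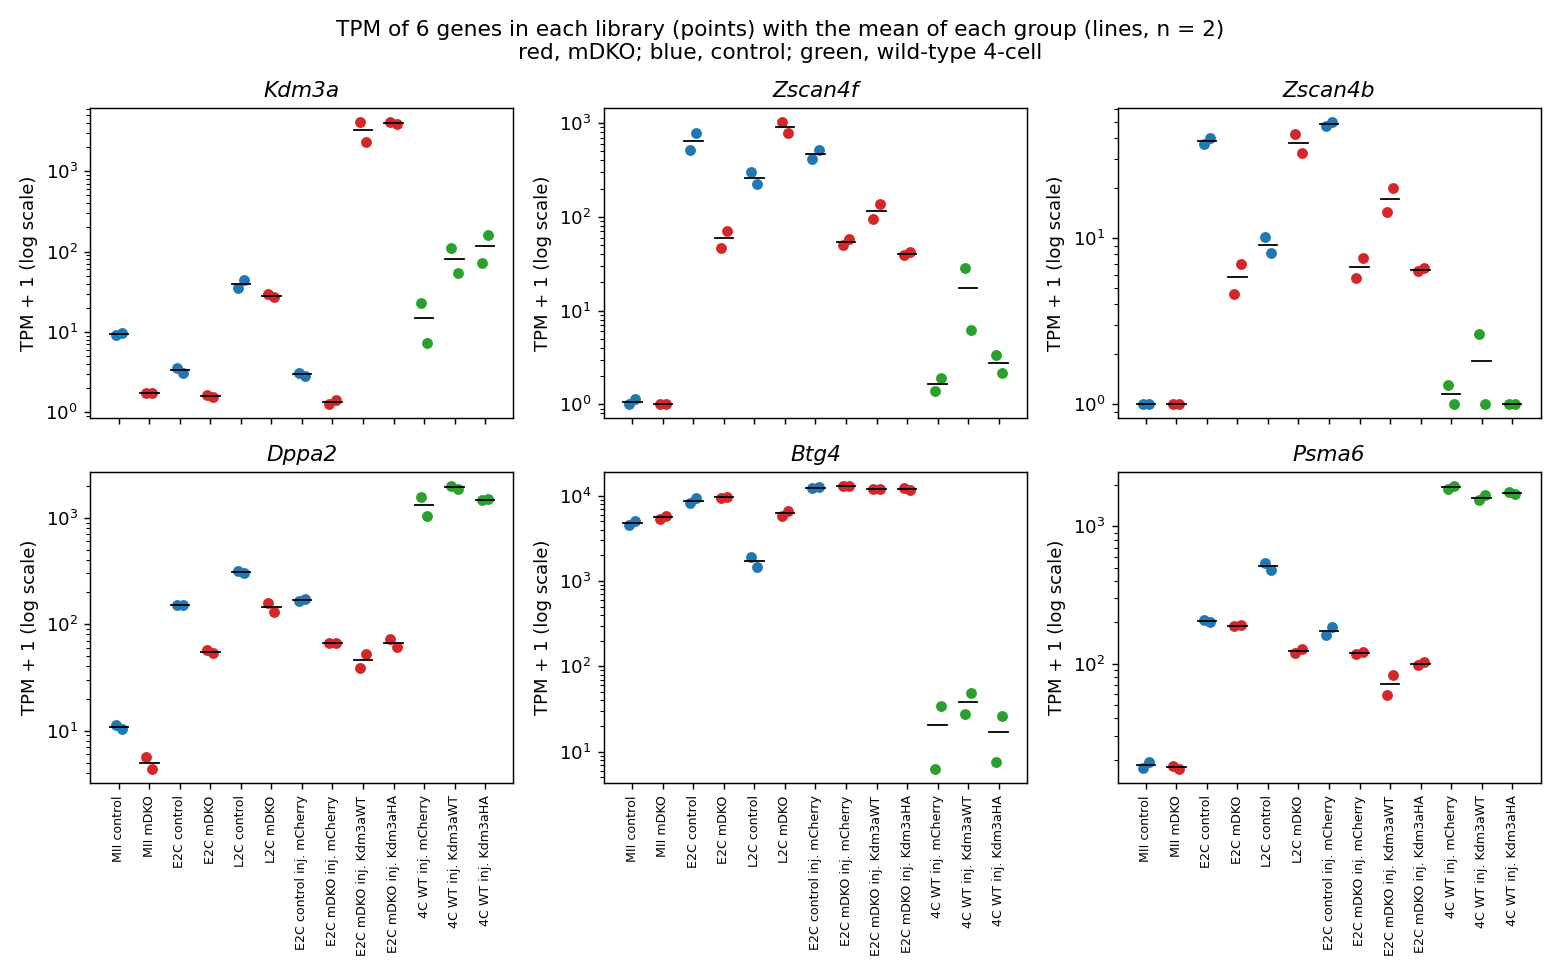
TPM plus 1 on a log axis of Kdm3a, Zscan4f, Zscan4b, Dppa2, Btg4 and Psma6 in each library (points), with group means as lines, mDKO groups in red, control groups in blue and wild-type 4-cell groups in green. Kdm3a lay below 1 TPM in all mDKO MII and E2C libraries without injected Kdm3a, and Zscan4f averaged 58.0 TPM in mDKO against 649 in control E2C embryos.

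Whether loss of the 2 demethylases already changed the oocyte was asked at MII. Kdm3b fell by 3.25 ± 0.18, adjusted p = 0.00378, and Kdm3a fell by 2.46 ± 0.21, adjusted p = 0.00804. The related gene Jmjd1c had a log2 fold change of -0.22 ± 0.22, adjusted p = 0.585, and did not pass. Germline genes that G9a or DNA methylation represses in other cells formed the list with the most members lower: 5 of 22 tested members fell, 0 rose and 17 did not pass. They included the tubulin gene Tuba3b, which fell by 3.83 ± 0.21 from 23.1 ± 3.17 to 0.683 ± 0.00871 TPM, and Tex19.1, a gene of transposon control in the germline, which fell by 2.85 ± 0.09 from 279 ± 15.1 to 37.8 ± 1.78 TPM. Sycp3 and Sycp1, which encode parts of the synaptonemal complex, also fell, Sycp3 by 1.54 ± 0.17 and Sycp1 from 9.45 ± 0.00893 to 3.24 ± 0.181 TPM.

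Over all genes, 91 of 10765 were higher and 367 lower in mDKO oocytes, 47 and 220 of them by at least 2-fold. Leaving out predicted-gene and clone names and genes under a mean TPM of 5, the highest changes were of Nfkbiz, a nuclear modulator of NF-kappaB (chromosome 16, 55811375 to 55838954), which rose by 3.59 ± 0.07, adjusted p = 1.77e-04, from 80.9 ± 0.590 to 984 ± 12.4 TPM, of Trpc5os (2.72 ± 0.21) and of the protease inhibitor gene Serpinb3a (2.27 ± 0.13). The lowest of these genes were Susd3 (chromosome 13, 49230511 to 49248706), which fell by 4.87 ± 0.29, adjusted p = 0.00484, the spindle-associated Fam83d (-4.73 ± 0.23), Urb1 (-4.71 ± 0.20) and the ribosome rescue factor Pelo (-4.65 ± 0.22). Of the regulators of genome activation, 3 of 17 fell, 7 when adjusted over the list alone, and the transcription factor gene Tfap2c fell by 1.74 ± 0.12. The imprinted gene Phlda2 fell by 2.02 ± 0.26 and was the only member called among 17 imprinted genes.

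The germline list had a median log2 fold change of -0.58 and 12 lower members when adjusted over the list alone (adjusted p = 0.00223, and adjusted p = 0.835 with an estimated correlation). Cytosolic ribosomal proteins had 5 of 76 members higher, among them Rplp1 at 1.13 ± 0.17, 5 when adjusted over the list alone, and a median of 0.22 (adjusted p = 1.50e-05, and 0.835 as the adjusted p with an estimated correlation). The ribosomal call ended without control replicate 1 and without mDKO replicate 2 (adjusted p = 0.181 and 0.0517, with 6.48e-13 to 0.181 over its alternatives), and 2 members were higher without control replicate 2 and 0 without mDKO replicate 1. Of 54 oocyte and maternal-effect genes limma called 0 higher, where 2657 of all genes had an unadjusted p under 0.05, and 2 lower, the meiotic kinase gene Aurkc (-0.74 ± 0.07) and Nlrp4b (-0.55 ± 0.07), with 3 higher and 2 lower when adjusted over the list alone. The list's median was 0.23 and its test upward (adjusted p = 1.71e-04, and adjusted p = 0.835 with an estimated correlation). Under size-factor scaling 2 of its members were called higher and 2 lower, and without control replicate 1 there were 8 higher and 2 lower, and 1, 0 and 1 lower without control replicate 2 and mDKO replicates 1 and 2. With all 12 uninjected libraries in 1 fit 9 of 31 germline genes were lower, and 5 oocyte genes higher and 1 lower. Of the early 2-cell list only 9 members were tested in oocytes, and Zfp809 (-1.69 ± 0.27) alone fell; the list's median was 0.03, its mean -0.19 and its test downward (adjusted p = 0.772). Of the H3K9 methylation machinery, 1 of 22 members fell, the demethylase gene Kdm7a at -0.91 ± 0.11. Lower germline members numbered 3 and 2 without control replicates 1 and 2, and 2 and 3 without mDKO replicates 1 and 2, and 1 regulator of genome activation fell without any 1 of these libraries. The counts over all genes rested on single libraries as well: without control replicate 1 there were 300 calls, 155 of them higher, without control replicate 2 there were 116, without mDKO replicate 1 there were 42, and without mDKO replicate 2 there were 128. Of 43 named genes called, 29 lost the call without mDKO replicate 1, where Kdm3a had an adjusted p of 0.0581 (4.59e-04 to 0.0581 over its alternatives), and 18 without mDKO replicate 2. Of the 38 still tested without a control library, 9 and 16 lost it without control replicates 1 and 2.

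At E2C, the stage of minor genome activation, most early 2-cell genes were lower in mDKO embryos. Of 43 tested members 35 fell, 0 rose and 8 did not pass (adjusted p = 0.36 for the list with an estimated correlation). Zscan4f (chromosome 7, 11397915 to 11402318), of a gene family active in 2-cell embryos and linked to telomere upkeep, fell by 3.46 ± 0.24, adjusted p = 1.33e-04, from 649 ± 181 to 58.0 ± 17.0 TPM. Zscan4a fell by 3.31 ± 0.25, and the predicted genes Gm2016 and Gm5662 fell by 3.99 ± 0.27 and 3.27 ± 0.16. The regulators Dppa2 (chromosome 16, 48310274 to 48319513) and Dppa4, which act upstream of Dux, fell by 1.45 ± 0.14, adjusted p = 6.45e-04, and 1.70 ± 0.25, adjusted p = 0.00381. Zscan4, Usp17l, Obox and Xlr genes have near-identical copies that share reads, so the value of any single copy is uncertain.

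The list had a median log2 fold change of -1.80, and 38 members lower and 2 higher when adjusted over the list alone (adjusted p = 1.18e-25; adjusted p = 0.0175 in fry). Of the Obox family, 4 of 9 fell, 5 lower and 2 higher when adjusted over the list alone, with Obox6 at -1.79 ± 0.30 and Obox3 at -1.53 ± 0.24 (adjusted p = 0.087). The Obox list passed without control replicate 1, without mDKO replicate 2 and with all 12 uninjected libraries in 1 fit (adjusted p = 0.00401, 0.00587 and 0.0393, with 0.00401 to 0.271 over its alternatives), and without control replicate 2 only 1 member fell. Among germline genes 8 of 26 fell and 1 rose, 11 and 1 when adjusted over the list alone (adjusted p = 0.00412, and adjusted p = 0.36 with an estimated correlation). Tex101, a sperm-surface protein gene, fell by 2.75 ± 0.24 and Tex19.1 by 2.07 ± 0.18. Of 54 oocyte and maternal-effect genes 10 rose, 1 fell and 43 did not pass, 14 higher and 2 lower when adjusted over the list alone (adjusted p = 0.00135, and adjusted p = 0.36 with an estimated correlation). The number that rose was 4 and 3 without control replicates 1 and 2, and 18 without mDKO replicate 1, and 5 fell without mDKO replicate 2. H1foo, the oocyte linker histone gene (chromosome 6, 115944931 to 115950242), rose by 1.83 ± 0.11, adjusted p = 1.11e-04, and Zar1, a gene of maternal mRNA storage, by 1.47 ± 0.19. In the H3K9 methylation machinery 3 of 21 members rose: the corepressor gene Trim28 by 1.98 ± 0.32, Mphosph8 by 1.25 ± 0.20 and Uhrf1 by 1.02 ± 0.23 (5 higher and 2 lower when adjusted over the list alone; adjusted p = 0.048; adjusted p = 0.608 with an estimated correlation). The call of this list ended with a pseudocount of 0.1 (adjusted p = 0.0532), without control replicate 2 (adjusted p = 0.121, with 0 members called by limma) and without mDKO replicate 1 (adjusted p = 0.0682), over a range of 0.0138 to 0.121. Those that rose numbered 9 without mDKO replicate 2 and 2 without control replicate 1, and 5 with all 12 uninjected libraries in 1 fit. Without a filter on low TPM 0 of 25 members were called by limma, where 3273 of all genes had an unadjusted p under 0.05 with the filter. The proteasome list had 3 of 31 members higher and 1 lower, the same counts when adjusted over the list alone (adjusted p = 0.0281, and adjusted p = 0.608 with an estimated correlation). Its call ended without control replicate 2 and without mDKO replicate 2 (adjusted p = 0.0556 and 0.306, with 0.00323 to 0.306 over its alternatives), and 1 member rose without either control replicate and 7 without mDKO replicate 1.

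In total 599 of 11140 genes were higher and 1001 lower, 273 and 663 of them by at least 2-fold. Kdm3a fell by 1.06 ± 0.26, adjusted p = 0.0309, Jmjd1c stood at 0.23 ± 0.26, adjusted p = 0.613, and Kdm3b was too low to be tested. The highest changes included microRNA entries, which are doubtful in a polyA TPM table, the steroid synthesis gene Hsd3b1 (chromosome 3, 98842356 to 98859794), which rose by 4.02 ± 0.33, adjusted p = 2.55e-04, from 0.114 ± 0.161 to 17.7 ± 7.32 TPM, Sumo2 (2.32 ± 0.15), Nfkbiz, at 10.1 ± 0.0777 TPM against 1.27 ± 0.158, and the metallothionein gene Mt1 (2.25 ± 0.15). The lowest included Susd3 (-4.72 ± 0.39), the X-linked Xlr3c (-4.63 ± 0.62) and Xlr3b (-4.49 ± 0.33), the RNA export gene Nxt2 (-4.18 ± 0.24) and Sult5a1 (-3.51 ± 0.35). Of 4 tested cumulus and granulosa cell markers, Serpine2 (1.06 ± 0.15) and the steroid enzyme gene Cyp11a1 (1.09 ± 0.28) were higher in the same mDKO libraries in which the early 2-cell genes were lower. Without mDKO replicate 2 the count of calls was 3214, and without control replicates 1 and 2 it was 363 and 282. Of the 72 called named genes still tested without a control library, 26 and 37 lost the call without control replicates 1 and 2, and of 76 still tested 1 lost it without mDKO replicate 2.

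The genes called at MII and at E2C, which share no library, were compared over 9331 genes tested in both. Of the genes lower in oocytes and tested at both stages, 130 were also lower at E2C where independent lists would share 22.8, and 2 were higher. Susd3, Tex19.1 and Phlda2 were among them, with E2C changes of -4.72, -2.07 and -2.37. Of the higher genes 29 were shared, against 5.18 for independent lists, and 4 went the other way. Nfkbiz, Mt1 and Trpc5os were higher at both stages. The log2 fold changes had a Pearson r of 0.383 and a Spearman rho of 0.293 across genes, which are not independent replicates.

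At L2C, the stage of major genome activation, most ribosomal protein, ribosome biogenesis and proteasome genes were lower in mDKO embryos and most oocyte genes were higher. None of these 4 lists passed with an estimated correlation (adjusted p = 0.0823, 0.375, 0.195 and 0.205). Of 77 cytosolic ribosomal protein genes, 74 fell, 0 rose and 3 did not pass. Rpl14 (chromosome 9, 120571517 to 120574653) fell by 2.23 ± 0.17, adjusted p = 2.38e-04, from 199 ± 4.76 to 42.2 ± 9.31 TPM, and Rps18 by 2.18 ± 0.14. Together these genes made up 5.86% and 5.74% of the TPM of control replicates 1 and 2, and 2.56% and 2.48% of the mDKO libraries. The ribosome biogenesis list had 38 of 41 members lower and 0 higher, with the RNA helicase gene Ddx21 at -1.89 ± 0.17 and Ftsj3 at -1.86 ± 0.19. Proteasome genes fell in 25 of 31 cases and rose in 0, Psma6 (chromosome 12, 55384222 to 55418459) by 2.04 ± 0.11, adjusted p = 1.51e-04.

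RNA polymerase II and spliceosome genes had 29 of 50 members lower and 3 higher, with Polr2h, a subunit shared by the RNA polymerases, at -2.62 ± 0.13. Oocyte and maternal-effect genes had 44 of 55 members higher and 1 lower: H1foo rose by 2.17 ± 0.17 and Bcl2l10, an apoptosis regulator of oocytes, by 2.16 ± 0.12. Btg4 (chromosome 9, 51102147 to 51119924), an adaptor of maternal mRNA deadenylation, rose by 1.88 ± 0.14, adjusted p = 2.47e-04, from 1694 ± 319.7 to 6185 ± 486 TPM. Early 2-cell genes, lower at E2C, were now higher in 28 of 47 cases and lower in 4, with AF067061 at 2.73 ± 0.16 and Zscan4b at 2.03 ± 0.21. The regulators of genome activation had 10 of 21 lower and 3 higher, among them Dppa4 (-1.47 ± 0.11), Nr5a2 (-1.32 ± 0.22) and Dppa2 (-1.12 ± 0.13). In the Obox family Obox1 (2.41 ± 0.12), Obox7 (2.41 ± 0.12) and Obox5 (2.07 ± 0.20), abundant in oocytes, rose, while Obox8 fell (-1.90 ± 0.16); 5 of 9 were higher and 3 lower.

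Adjusted over the list alone, the counts lower were 74 for ribosomal proteins, 39 for biogenesis, 25 for the proteasome and 30 for polymerase and spliceosome, with 3 higher in the last. The medians were -1.25, -1.05, -1.02 and -0.63. Their adjusted p-values were 8.00e-29, 3.10e-13, 8.04e-09 and 3.99e-06, and that of polymerase and spliceosome was 0.307 with an estimated correlation. Oocyte genes had 45 higher and 2 lower when adjusted over the list alone and a median of 1.11 (adjusted p = 6.36e-15). Early 2-cell genes had 29 and 4 when adjusted over the list alone and a median of 0.85 (adjusted p = 1.65e-06; adjusted p = 0.519 with an estimated correlation). The regulators had 12 lower and 3 higher when adjusted over the list alone (adjusted p = 0.0428; adjusted p = 0.519 with an estimated correlation), a call that ended under size-factor scaling (adjusted p = 0.0535), without control replicates 1 and 2 (adjusted p = 0.0721 and 0.0693) and without mDKO replicates 1 and 2 (adjusted p = 0.0516 and 0.0740), over a range of 0.00638 to 0.0740. Cell cycle genes had 14 of 34 lower and 3 higher, the same counts when adjusted over the list alone, with the mitotic kinase gene Cdk1 at -0.99 ± 0.13 (adjusted p = 0.0261; adjusted p = 0.392 with an estimated correlation), and the call ended without mDKO replicate 2 (adjusted p = 0.0635, with 0.00273 to 0.0635 over its alternatives). In fry, which does not compare a list with other genes, ribosomal proteins had an adjusted p of 6.41e-04, the proteasome 0.00486 and oocyte genes 0.00486.

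Over all genes 2409 of 12606 were higher and 2933 lower at L2C, 1194 and 1517 of them by at least 2-fold. Kdm3b fell by 1.03 ± 0.32, adjusted p = 0.0383, while Kdm3a (-0.49 ± 0.17, adjusted p = 0.0573) and Jmjd1c (-0.10 ± 0.24, adjusted p = 0.747) did not pass. Leaving out control replicate 1, control replicate 2 or mDKO replicate 1 ended the Kdm3b call (adjusted p = 0.0792, 0.129 and 0.222), as did a pseudocount of 0.1 and no filter on low TPM (adjusted p = 0.0557 and 0.105), over a range of 0.0149 to 0.222. Without control replicate 1 Kdm3a passed (adjusted p = 0.0265, with 0.0265 to 0.206 over its alternatives). Of 87 called named genes still tested, 4 lost the call without control replicate 1 and 4 without control replicate 2, and of 89, 3 and 2 lost it without mDKO replicates 1 and 2. Several of the largest changes were small nucleolar RNA or microRNA entries, which are doubtful in a polyA TPM table. Among the others, the transcription factor gene Tfec (3.70 ± 0.30) and the glutathione transferase gene Mgst1 (3.21 ± 0.26) were among the highest. Eif3j1 (-5.90 ± 0.28), Plac9a, which mDKO libraries listed at 0, Defb42 (-4.01 ± 0.24) and Susd3 (-3.41 ± 0.28) were among the lowest. Of 6 cumulus and granulosa markers 2 were higher in mDKO embryos, Serpine2 (1.46 ± 0.17) and Inhba, which control libraries listed at 0, beside the ribosomal and oocyte gene groups above.

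**Figure D2:**
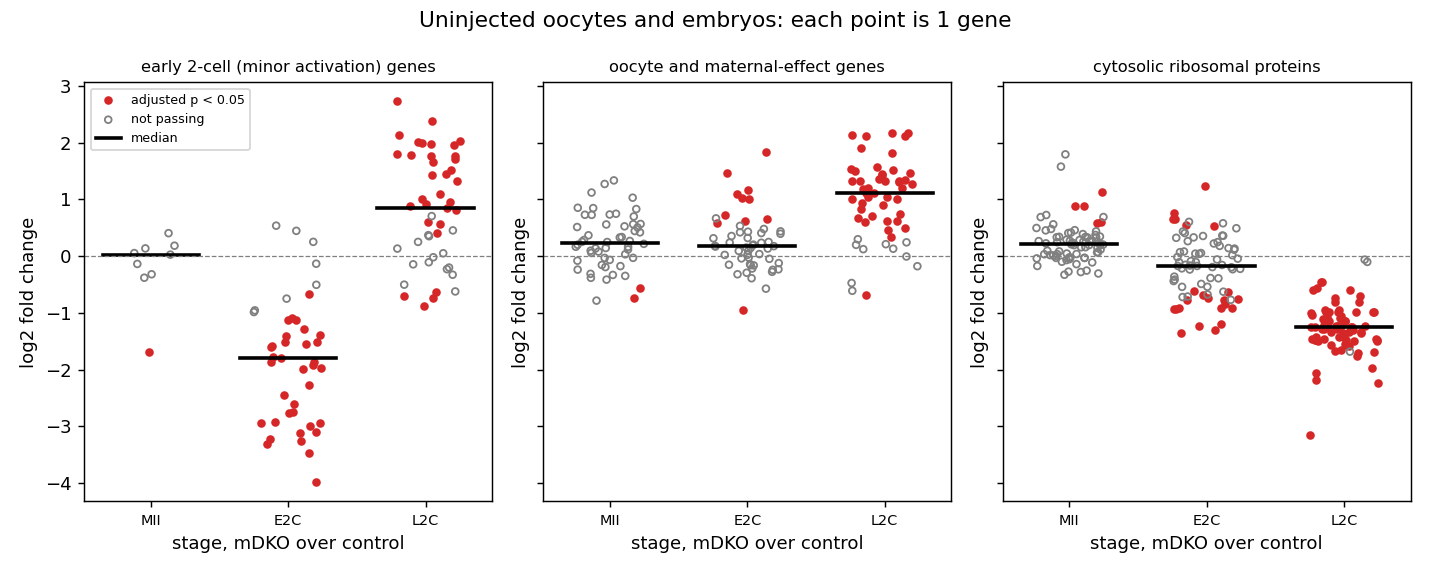
Log2 fold changes of mDKO over control for each tested member (points) of the early 2-cell, oocyte and maternal-effect and ribosomal protein lists at MII, E2C and L2C, with members past the threshold in red, those not passing as open grey points and the median as a black line. The early 2-cell median was -1.80 at E2C and 0.85 at L2C, and the ribosomal protein median was -1.25 at L2C.

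The mDKO effects at E2C and L2C were set side by side over 10460 genes tested in both, again without a shared library. Of the genes lower at E2C 324 were lower at L2C, where independent lists would share 213.7, and 153 were higher. Of those higher at E2C 243 were also higher at L2C, where 123.8 would be shared, and 137 were lower. Across genes, the Pearson r was 0.173 and the Spearman rho 0.163. Dppa2, Dppa4, Tex19.1 and Susd3 were lower at both stages, whereas Zscan4f fell at E2C by 3.46 ± 0.24 and Zscan4b rose at L2C by 2.03 ± 0.21. The difference of the 2 effects was itself tested, and 3678 of 14316 genes passed, 1889 with a higher and 1789 with a lower effect at L2C. The early 2-cell list had 36 of 47 members with a higher effect and 0 with a lower one, 38 and 0 when adjusted over the list alone (adjusted p = 2.41e-23, and adjusted p = 0.0295 with an estimated correlation). AF067061 differed by 5.34 ± 0.26 and Zscan4f by 5.26 ± 0.35. Of 85 or 86 called named genes still tested, between 6 and 11 lost the call without any 1 of the 8 E2C and L2C libraries.

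Injected embryos were used to ask whether Kdm3a RNA changes mDKO embryos. With mCherry alone, most early 2-cell genes were again lower in mDKO than in control embryos: 40 of 43 fell, 0 rose and 3 did not pass (adjusted p = 0.13 for the list with an estimated correlation). Zscan4a (chromosome 7, 10794241 to 10799065) fell by 3.69 ± 0.19, adjusted p = 5.69e-06, from 168 ± 1.79 to 12.2 ± 2.23 TPM, Zscan4f fell by 3.09 ± 0.19, Dppa2 by 1.34 ± 0.15 and Tex19.1 by 2.16 ± 0.13. Hsd3b1, Cd52, a surface glycoprotein gene of leukocytes, and Apoe were listed at 0 in control embryos and at 79.7 ± 0.370, 359.9 ± 102 and 28.0 ± 4.92 TPM in mDKO mCherry embryos. The galectin gene Lgals1 rose by 5.67 ± 0.31 and Spp1, the osteopontin gene, by 4.89 ± 0.22. Of 8 cumulus and granulosa markers 5 rose and 0 fell (adjusted p = 0.279 for the list with an estimated correlation), among them Serpine2 (2.43 ± 0.11), and the inhibin subunit genes Inhba and Inha, which control libraries listed at 0. Without mDKO mCherry replicate 1 only 1 of 5 cumulus markers tested was higher. Of 3 tested blood cell markers the lysozyme gene Lyz2 was higher (3.48 ± 0.35) and the globin gene Hba-a1 lower (-1.91 ± 0.56).

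The early 2-cell list had a median of -1.56, with 40 lower and 1 higher when adjusted over the list alone (adjusted p = 7.75e-19). The cumulus list had a median of 1.15 and 5 higher when adjusted over the list alone (adjusted p = 0.032; adjusted p = 0.279 with an estimated correlation), a call that ended with a pseudocount of 0.1 and without a filter on low TPM (adjusted p = 0.0612 and 0.138), without control replicate 1 (adjusted p = 0.0532) and without mDKO mCherry replicate 1 (adjusted p = 0.370, with 1 of 5 members higher) and with only the 4 libraries compared (adjusted p = 0.0811), over a range of 0.0302 to 0.922, the last with mDKO Kdm3aHA in place of the mDKO mCherry libraries. Without mDKO mCherry replicate 2 too few members were left for a test. Germline genes had 14 of 26 lower and 2 higher, the same counts when adjusted over the list alone, with Sycp3 at -2.18 ± 0.12 (adjusted p = 0.00439; adjusted p = 0.279 with an estimated correlation). Ribosomal protein genes went both ways, 20 of 77 higher and 10 lower, 17 and 9 when adjusted over the list alone (adjusted p = 0.642), with 6, 5, 3 and 3 lower without control replicates 1 and 2 and mDKO replicates 1 and 2, and 10 higher without mDKO replicate 1. Oocyte genes also did, 21 of 54 higher and 11 lower, in the same numbers when adjusted over the list alone, with Zar1 at 2.94 ± 0.23 (adjusted p = 0.673). In total 2946 of 10960 genes were higher and 2195 lower, 1531 and 602 of them by at least 2-fold. Kdm3a fell by 1.15 ± 0.23, adjusted p = 0.00354, and Jmjd1c stood at 0.22 ± 0.16, adjusted p = 0.303. With the mDKO Kdm3aHA libraries in place of the mDKO mCherry libraries, an alternative chosen after seeing the data, 1862 genes were higher and 2202 lower; 3174 genes were called in the same direction in both and 42 in opposite directions. Both contrasts use the same control libraries: 1636 genes were higher in both, where independent lists would share 500.5. Simulated groups with no effect shared 0.05 on average over 20 draws. Few genes pass when there is no effect, so that count cannot show what the shared controls add to the 1636. The r of the log2 fold changes was 0.765, against 0.501 with no effect. The covariance of the log2 fold changes was 0.521, against 0.0232 with no effect, and part of the excess may come from the shared controls, which cannot be split. Without mDKO mCherry replicates 1 and 2 the calls numbered 3117 and 3264. Of 92 called named genes still tested, 4 and 2 lost the call without control replicates 1 and 2, and of 88, 4 and 5 lost it without mDKO replicates 1 and 2.

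Genes called without injection were compared with these calls over 10424 genes tested in both sets of libraries, which share none. Of the lower genes 594 were shared, where independent lists would share 189.6, and 64 went the other way, so that 64.3% of the genes lower without injection were lower again. Of the higher genes 384 were shared, against 152.2, and 11 went the other way, which is 66.1% of those higher without injection. The Pearson r across genes was 0.483 and the Spearman rho 0.443. The E2C-lower set had 401 of 594 members lower and 30 higher, with a median of -1.01 (adjusted p = 5.72e-27; adjusted p = 6.51e-04 with an estimated correlation). The E2C-higher set had 199 of 256 higher and 1 lower, with a median of 1.02 (adjusted p = 7.27e-24; adjusted p = 0.0324 with an estimated correlation). Among stage sets, minor-activation genes were lower in 247 and higher in 38 of 554 cases (median -0.58, adjusted p = 1.24e-12), and major-activation genes, of which only 102 could be tested at E2C, were higher in 57 and lower in 4 (median 0.82, adjusted p = 6.74e-06), beside 5 of 8 cumulus markers higher in the same mDKO mCherry libraries. The major-activation set was chosen for a low TPM in control E2C embryos. Its members therefore tend to pass the filter through groups where they are higher, which favours this direction. Without a filter on low TPM the call ended (adjusted p = 0.152, with 2.49e-06 to 0.152 over its alternatives), so the test cannot decide whether these genes rose as a set. Of 2133 maternal-decay genes 710 were higher and 277 lower, with a median of 0.18 (adjusted p = 0.00325; adjusted p = 0.318 with an estimated correlation).

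Part of the early 2-cell genes were higher in mDKO embryos injected with Kdm3aWT than in those with mCherry. Of 43 tested members 20 rose, 1 fell and 22 did not pass (adjusted p = 0.0989 for the list with an estimated correlation). After Kdm3a itself (11.18 ± 0.23, adjusted p = 1.09e-07), which includes the injected RNA, the highest change outside predicted-gene names, 8 of which were passed over, was of Zscan4a, which rose by 1.75 ± 0.19, adjusted p = 0.00109, from 12.2 ± 2.23 to 43.3 ± 3.68 TPM. Zscan4b (1.36 ± 0.20), the deubiquitinase gene Usp17lb (1.26 ± 0.14) and Zscan4f (1.07 ± 0.19) were also higher. The regulators Dppa4 and Dppa2 fell by 1.13 ± 0.25 and 0.57 ± 0.15 below mDKO mCherry. Among 8 cumulus and granulosa markers 5 fell and 0 rose, and Cd52 (-6.42 ± 0.50), Ifitm2 (-5.06 ± 0.34) and Lgals1 (-4.84 ± 0.31) were the lowest of the named genes, in the same comparison in which the early 2-cell genes rose.

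In all 104 of 10960 genes were higher and 1184 lower than in mDKO mCherry embryos. The median of all genes stood at -0.19, and under size-factor scaling at -0.02, with 249 higher and 592 lower, so that the share of lower calls went from 91.9% to 70.4%. Relative to the median of all genes the early 2-cell median was 0.76, and it was 0.79 under the scaling. The list had 24 members higher and 2 lower when adjusted over the list alone (adjusted p = 8.16e-21; adjusted p = 0.00697 in fry). Of the Obox family 2 of 9 rose, 5 when adjusted over the list alone (adjusted p = 2.09e-07; adjusted p = 0.0989 with an estimated correlation), Obox3 by 0.71 ± 0.17. Ribosomal protein genes had 36 of 77 lower and 0 higher, 47 lower when adjusted over the list alone, Rps19 at -2.53 ± 0.18, and a list median of -0.34 relative to all genes (adjusted p = 5.30e-07; adjusted p = 0.0989 with an estimated correlation). The proteasome had 14 of 31 lower and 1 higher, 19 and 1 when adjusted over the list alone, also at -0.34 (adjusted p = 9.26e-04; adjusted p = 0.125 with an estimated correlation). Of the biogenesis genes 6 of 37 fell, 10 when adjusted over the list alone (adjusted p = 0.0263; adjusted p = 0.391 with an estimated correlation), and the call ended under scaling (adjusted p = 0.0600), without Kdm3aWT replicate 1 (adjusted p = 0.0601) and with only the 4 libraries compared (adjusted p = 0.0646), over a range of 0.00129 to 0.0646 with mDKO mCherry as the reference. The cumulus list, at -0.54 relative to all genes and with 5 lower when adjusted over the list alone, had an adjusted p of 0.0101, and an adjusted p = 0.137 with an estimated correlation. The call ended without a filter on low TPM (adjusted p = 0.120), without Kdm3aWT replicate 2 (adjusted p = 0.138) and without mCherry replicate 1, where 0 of 5 members were called by limma and the list stood at 0.08 (adjusted p = 0.634), over a range of 0.00336 to 0.634 with mDKO mCherry as the reference. With all libraries 3182 of all genes had an unadjusted p under 0.05. Without mCherry replicates 1 and 2, 4 and 13 early 2-cell genes were higher, 5 and 16 ribosomal protein genes lower and 1 and 2 proteasome genes lower. Without Kdm3aWT replicate 1, 9 proteasome genes and 3 of 7 cumulus markers were lower. Biogenesis genes lower numbered 1 and 11 without Kdm3aWT replicates 1 and 2 and 0 and 2 without the mCherry replicates. Without Kdm3aWT replicate 1 the calls numbered 788, without mCherry replicate 1 they numbered 91 and without mCherry replicate 2 they numbered 228. Of 67 named genes called, 20 and 6 lost the call without Kdm3aWT replicates 1 and 2, and of 61 still tested 43 and 31 lost it without mCherry replicates 1 and 2.

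Embryos injected with Kdm3aHA, a construct that the labels do not explain, had Kdm3a at 11.54 ± 0.23 over mDKO mCherry. Of 43 early 2-cell genes 3 rose and 5 fell, with Gm2016 at -1.22 ± 0.20, Dux, the homeobox activator of this programme, at -0.96 ± 0.14, and Gm20767 at 0.76 ± 0.15. The list's median was -0.05 and its mean -0.10, with camera upward (adjusted p = 0.629) and fry downward (adjusted p = 0.693), and 4 higher and 6 lower when adjusted over the list alone. Other changes were of Oog1, an oocyte gene, at 3.82 (adjusted p = 0.0455), and of Cd52 (-7.94 ± 0.50) and Lgals1 (-6.11 ± 0.31), which fell as with Kdm3aWT. Hsd3b1, at 79.7 TPM in mDKO mCherry, was listed at 0. Of the ribosomal protein genes 26 of 77 fell and 1 rose, 34 and 2 when adjusted over the list alone (adjusted p = 1.60e-05; adjusted p = 0.196 with an estimated correlation), beside 5 of 8 cumulus markers lower and 0 higher, 7 lower when adjusted over the list alone (adjusted p = 3.19e-05; adjusted p = 0.163 with an estimated correlation). Lower ribosomal protein genes numbered 16 without either Kdm3aHA replicate, and 6 and 8 without mCherry replicates 1 and 2, and 1 of 5 cumulus markers was lower without mCherry replicate 1. Both constructs are set against the same pair of mCherry libraries. In all 169 genes were higher and 1018 lower, 85.8% lower, and under size-factor scaling 284 and 792, 73.6% lower. Without Kdm3aHA replicate 1 the calls numbered 632, without mCherry replicate 1 they numbered 216 and without mCherry replicate 2 they numbered 279. Of 65 named genes called, 23 and 15 lost the call without Kdm3aHA replicates 1 and 2, and of 58 still tested 30 lost it without mCherry replicate 1 and 30 without mCherry replicate 2.

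Set directly against Kdm3aHA, Kdm3aWT embryos had part of the early 2-cell genes higher in a fit in which the mCherry libraries help to set the spread. Of 43 members 18 were higher, 1 lower and 24 did not pass (adjusted p = 0.206 for the list with an estimated correlation). With only the 4 libraries compared 2 of 40 were higher and 0 lower, and without a filter on low TPM 3 were higher. Zscan4a was higher by 1.76 ± 0.19 (adjusted p = 0.0093), at 43.3 ± 3.68 TPM with Kdm3aWT and 12.3 ± 3.32 with Kdm3aHA. Zscan4c was higher by 1.66 ± 0.21 and Usp17lb by 1.51 ± 0.14, and Zscan4f was at 115 ± 30.8 against 39.3 ± 1.98 TPM. Kdm3a itself differed by -0.36 ± 0.23, adjusted p = 0.372, and stood at -0.78 and 0.05 without Kdm3aWT replicates 1 and 2. Among 8 cumulus markers limma made 0 calls, with Serpine2 at 0.01 ± 0.11 and a list median of 0.13 (adjusted p = 0.18). Of all genes 2537 had an unadjusted p under 0.05. The early 2-cell list's median log2(TPM + 1) per library was 4.35 and 4.41 with Kdm3aWT and 3.45 and 3.42 with Kdm3aHA, beside 3.65 and 3.80 with mCherry and 5.57 and 5.66 in control embryos. Median per-gene changes from mDKO mCherry were 36.7% of the median per-gene gap to control with Kdm3aWT and -3.46% with Kdm3aHA. Relative to the median of all genes the list stood at 0.76 with Kdm3aWT and 0.03 with Kdm3aHA. The Kdm3aHA sign thus turns with the shift of all genes.

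The list's median difference was 0.73, with 24 higher and 5 lower when adjusted over the list alone (adjusted p = 1.54e-14; adjusted p = 0.0106 in fry). Members higher numbered 4 and 3 without Kdm3aHA replicates 1 and 2 and 9 without Kdm3aWT replicate 1, and 2 of 40 with only the 4 libraries compared, where the list still passed (adjusted p = 2.18e-16, with 6.06e-17 to 3.53e-08 over its alternatives). Obox genes had 1 of 9 higher, 3 when adjusted over the list alone, Obox4 at 0.57 ± 0.12 (adjusted p = 0.00206; adjusted p = 0.281 with an estimated correlation), a call that ended without Kdm3aHA replicate 2 (adjusted p = 0.0840, with 7.95e-05 to 0.0840 over its alternatives). Without Kdm3aWT replicate 2 there were 2 Obox genes higher, and without any 1 of the other 3 libraries 0 by limma, where 2537 of all genes had an unadjusted p under 0.05 with all libraries. The biogenesis and proteasome lists had 3 of 37 and 5 of 31 members lower, 7 and 13 when adjusted over the list alone (adjusted p = 0.0371 and 0.0108; with an estimated correlation, adjusted p = 0.461 and 0.281), and the biogenesis call ended under size-factor scaling (adjusted p = 0.0605), without Kdm3aHA replicate 1 (adjusted p = 0.231) and without Kdm3aWT replicate 2 (adjusted p = 0.0872), over a range of 0.00310 to 0.231. Without Kdm3aWT replicate 2, 9 biogenesis and 12 proteasome genes were lower. Without Kdm3aWT replicate 1 these counts were 0 and 1, and without either Kdm3aHA replicate both were 0. With only the 4 libraries compared limma called 0 Obox, biogenesis and proteasome genes. Cdk1, the kinase gene of entry into mitosis, was lower at -1.26 ± 0.16. Over all genes 145 were higher and 216 lower, 59.8% lower, and under size-factor scaling 121 and 90, 42.7% lower. Among named genes the highest change was of Taf10, a subunit gene of the general factor TFIID, at 3.09 ± 0.39, with 323 ± 191 TPM for Kdm3aWT, and the lowest that of Oog1 at -5.21 (adjusted p = 0.0341). The count varied with single libraries: without Kdm3aHA replicates 1 and 2 there were 31 and 8 calls, and without Kdm3aWT replicates 1 and 2 there were 59 and 1493. Of 49 named genes called, 41, 45, 31 and 1 lost the call in these 4 cases.

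Genes lower at E2C without injection went both ways with either construct. Of 594 E2C-lower genes 40 rose and 56 fell with Kdm3aWT, a change of -8.78% of the gap, and 14 rose and 78 fell with Kdm3aHA, -17.1% of the gap. Relative to the median of all genes, which shifted as well, the set stood at 0.10 with Kdm3aWT, towards control, and at -0.09 with Kdm3aHA, and under size-factor scaling at 0.07 and -0.10, so that the sign of the Kdm3aWT share turns. With Kdm3aWT the median was -0.09 and the mean -0.10, while camera was upward (adjusted p = 7.65e-05; adjusted p = 0.0218 with an estimated correlation) and fry downward (adjusted p = 0.0331). Under size-factor scaling the camera call ended, with an adjusted p of 0.0580, with a range of 1.88e-05 to 0.0580 over the settings that keep mDKO mCherry as the reference. Between the constructs 37 were higher and 6 lower with Kdm3aWT (median 0.10, adjusted p = 1.19e-06; adjusted p = 0.0112 with an estimated correlation). E2C-higher genes fell in 60 of 256 cases and rose in 3 with Kdm3aWT (median -0.37, adjusted p = 0.00313; adjusted p = 0.454 with an estimated correlation), and in 28 and 4 with Kdm3aHA (adjusted p = 0.582). Against Kdm3aHA, 10 were lower and 5 higher with Kdm3aWT (adjusted p = 0.0102; adjusted p = 0.525 with an estimated correlation), and the call ended without Kdm3aHA replicate 2 (adjusted p = 0.109) and without Kdm3aWT replicate 1 (adjusted p = 0.0540), the range over its alternatives being 7.98e-07 to 0.109. Major-activation genes fell in 37 of 102 cases with Kdm3aWT and 34 with Kdm3aHA (adjusted p = 7.44e-05 and 5.72e-08), with medians of -0.65 and -0.63. Of 8 cumulus markers 5 fell with Kdm3aWT and 5 with Kdm3aHA, against 0 and 1 of 5 without mCherry replicate 1, and both contrasts use the same mDKO mCherry pair. The 102 major-activation genes tend to pass the filter through groups where they are higher, such as mDKO mCherry, so the filter favours a fall from that reference. Without a filter on low TPM the call for Kdm3aWT ended (adjusted p = 0.368, with 3.67e-10 to 0.368 over its alternatives). Minor-activation genes had 46 higher and 42 lower with Kdm3aWT, with a median of -0.10, camera upward (adjusted p = 2.40e-05) and fry downward (adjusted p = 0.00765); relative to all genes the median was 0.09, and under size-factor scaling the camera call ended (adjusted p = 0.0580, with 3.13e-04 to 0.0580 over its alternatives).

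**Figure D3:**
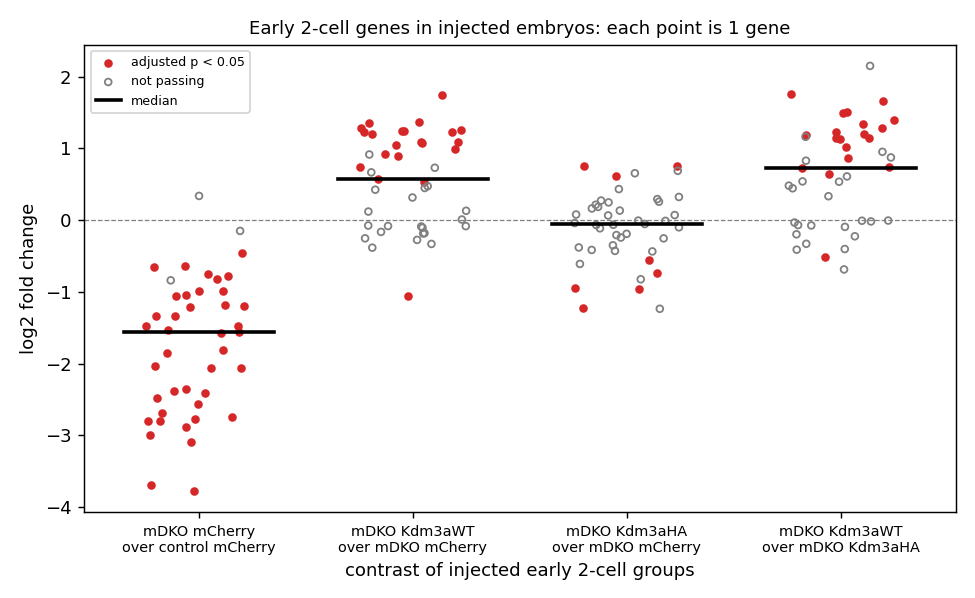
Log2 fold changes of the tested early 2-cell genes (points) in the 4 contrasts of injected E2C embryos, with members past the threshold in red, those not passing as open grey points and the median as a black line. The median was -1.56 for mDKO over control with mCherry, 0.57 for Kdm3aWT and -0.05 for Kdm3aHA over mDKO mCherry, and 0.73 for Kdm3aWT over Kdm3aHA.

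In wild-type 4C embryos extra Kdm3a was tested on an intact background, and no gene passed. Kdm3a stood at 2.58 ± 0.62, adjusted p = 0.49 with Kdm3aWT, and at 3.07 ± 0.62, adjusted p = 0.769 with Kdm3aHA. For Kdm3aWT over mCherry the smallest p-values were those of Esp24 (2.65 ± 0.37, adjusted p = 0.0824) among higher and of Tmsb15a, which Kdm3aWT libraries listed at 0, among lower genes. For Kdm3aHA over mCherry Tcstv3, an early 2-cell gene, stood at 3.26 ± 0.83 and Rps27 at -2.62 ± 0.64, and between the constructs Samt2 at 3.76 ± 0.57. Early 2-cell genes had a median of 1.56 with Kdm3aWT, 1.11 relative to the median of all genes and 1.13 under size-factor scaling, with 0 members past the threshold over all genes in limma and 9 of 41 higher when adjusted over the list alone (adjusted p = 2.03e-11; adjusted p = 0.529 with an estimated correlation). With Kdm3aHA the median was 0.63, 0.28 relative to all genes, 0.25 under size-factor scaling and 0.18 without a filter on low TPM, and 0 were higher when adjusted over the list alone (adjusted p = 0.691). Between the constructs it was 1.11, 1.03 relative to all genes, with 5 higher when adjusted over the list alone (adjusted p = 8.42e-16; adjusted p = 0.766 with an estimated correlation). Relative to all genes the Kdm3aWT median was 1.84 without mCherry replicate 1 and 0.37 without mCherry replicate 2, and 12 members were called higher without mCherry replicate 1, 1 without Kdm3aWT replicate 1 and 10 without Kdm3aWT replicate 2. The Kdm3aHA list turned with single libraries. It passed upward without mCherry replicate 1, at 0.63 with 2 members called (adjusted p = 0.0102), and without Kdm3aHA replicate 1, at 0.72 (adjusted p = 0.00263). It passed downward without mCherry replicate 2, at -0.42 (adjusted p = 7.71e-04), and without Kdm3aHA replicate 2, at -0.39 (adjusted p = 0.0200), over a range of 7.71e-04 to 0.787. Between the constructs the median was 0.48 and 1.62 without Kdm3aHA replicates 1 and 2 and 0.49 without Kdm3aWT replicate 1, and 1 and 6 members were called higher without Kdm3aWT replicates 1 and 2.

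The limma fit over 9669 genes made 0 calls in each of the 3 contrasts. At an unadjusted p under 0.05 there were 776 genes for Kdm3aWT over mCherry, 264 for Kdm3aHA over mCherry and 227 for Kdm3aWT over Kdm3aHA, where 483 would be reached by chance. The median of all genes stood at 0.44 and 0.35 in the contrasts with mCherry, at 0.07 and 0.05 under size-factor scaling, and at 0.17 and 0.14 without a filter on low TPM. Without mCherry replicate 1 these medians were 0.76 and 0.65, without mCherry replicate 2 they were 0.13 and 0.03, and that of Kdm3aHA was 0.22 without Kdm3aHA replicate 2. The mCherry replicate 2 library had 7649 genes at a TPM of 1 or more, the fewest of all, and 17.5% of its TPM in ribosomal proteins. Ribosomal protein genes had medians of -0.16 and -0.11 over mCherry, -0.61 and -0.46 relative to the median of all genes (adjusted p = 1.20e-20 and 4.17e-15; with an estimated correlation, adjusted p = 0.35 and 0.683). Relative to all genes these medians were -0.34 and -0.25 without a filter on low TPM, -0.31 and -0.16 without mCherry replicate 2, and that of Kdm3aHA -0.72 without mCherry replicate 1, and the Kdm3aHA call ended without Kdm3aHA replicate 2, at -0.22 (adjusted p = 0.0675, with 5.05e-25 to 0.0675 over its alternatives). Without mCherry replicate 1 the contrast of Kdm3aWT with mCherry gave 491 calls, without Kdm3aWT replicates 1 and 2 it gave 9 and 35, and Kdm3a itself passed without mCherry replicate 1 (adjusted p = 0.0398) and without Kdm3aWT replicate 2 (adjusted p = 0.0223), over a range of 0.0223 to 0.999. Kdm3aHA over mCherry gave 21 calls without mCherry replicate 1 and 2 without Kdm3aHA replicate 2, and Kdm3aWT over Kdm3aHA gave 12 and 23 without Kdm3aWT replicates 1 and 2.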

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

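Some tests in this part were chosen after the results were seen. They covered sharing of doubled genes with Kdm3aHA embryos, cumulus markers, doubled genes without injection, stage-differing genes and the level of Kdm3a. They also covered list members without single libraries or with other libraries in the fit.

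The effect of losing maternal KDM3A and KDM3B differed between E2C and L2C, by a test of the difference itself, for 3678 genes. Of these, 151 were lower at E2C and higher at L2C, and 136 higher at E2C and lower at L2C, with all 3 tests passed. The early 2-cell list had a median difference, L2C minus E2C, of 2.73. Lists with a lower effect at L2C included ribosome biogenesis (-1.21), ribosomal proteins (-1.03), the proteasome (-1.10) and polymerase and spliceosome (-0.69), and these 5 lists also passed with an estimated correlation. Those passing at the preset correlation alone were cell cycle (-0.50; adjusted p = 0.139 with an estimated correlation) and H3K9 methylation machinery (-0.45; adjusted p = 0.447) with a lower effect, and oocyte (0.78; adjusted p = 0.0542) and Obox genes (1.28; adjusted p = 0.279) with a higher one. Leaving out 17 predicted-gene and clone names, genes with the highest differences were Zscan4f at 5.26 ± 0.35, Zscan4c at 5.18 ± 0.56, Zscan4b at 4.79 ± 0.33, Zscan4d at 4.38 ± 0.36, Apoo-ps at 4.58 ± 0.62, Samt2 at 4.12 ± 0.37 and Usp17la at 3.88 ± 0.31. Those with the lowest were Eif3j1 at -9.59 ± 2.11, Plac9a at -5.76 ± 0.34, Sumo2 at -4.13 ± 0.16, Defb42 at -3.73 ± 0.36, Dnttip2 at -3.47 ± 0.23, Gpha2 at -3.42 ± 0.66, Wrb at -3.35 ± 0.36 and Cebpz at -3.32 ± 0.28. The small RNA entries Mir6992 at 7.11 ± 1.52, Snora69 at 6.24 ± 1.18, Snora30 at 4.16 ± 1.11, Mir1892 at -8.50 ± 2.55 and Mir7653 at -5.63 ± 0.25 also passed, and are doubtful in a polyA TPM table.

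At L2C the mDKO profiles were nearer to control E2C than control profiles were. Across genes, the mDKO r with the control E2C mean was 0.851 and 0.855, against 0.743 and 0.745 in L2C controls. Scaling of TPM by a few genes is argued against, since the ribosomal protein and oocyte list medians kept 96.2% and 104% under size-factor scaling. TPM cannot show a change in total RNA. Noise of the shared L2C controls is also argued against. The covariance of the mDKO effect with the control E2C minus L2C difference was 0.968. This was 18.0 times the 0.0538 that this noise adds, as reckoned from the spread between the control L2C libraries. Delayed progress through the 2-cell stage may contribute but cannot be told apart from a direct effect of the loss, since genes that differ between stages were called 1.66 times as often as others, 48.7% of 8144 against 29.3% of 2559, a ratio between the bounds set for either answer. Of stage-differing genes called, 91.6% lay on the E2C side in mDKO embryos.

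In injected embryos 1531 genes were at least doubled in mDKO mCherry over control mCherry, beside 5 of 8 tested cumulus and granulosa markers higher there, and 1 of 5 without mDKO mCherry replicate 1. RNA of such cells in the mDKO mCherry libraries is argued against as the cause of the whole pattern, since 62.0% of these genes were also higher in Kdm3aHA over control, against 7.93% on average, and 8.93% at most, over 20 simulated sets in which Kdm3aHA embryos had the control level of these genes and shared the control libraries; independent lists would share 260.1 genes. Whether such RNA is a source of the part not shared cannot be decided here. Of 8 tested markers 62.5% were higher in mDKO mCherry than in each of the 3 other groups, but 20 were listed. Those tested tend to pass the filter on low TPM through the libraries where they are high, which favours this result. The doubled genes higher in neither Kdm3a group numbered 376. GC content and transcript length are argued against, since 74.0% of the doubled genes stayed at a log2 fold change of 1 or more after correction, at a median of 1.28. The loss itself, acting without injection, would need a median of 0.5 or more in embryos without injection. The 1370 of these genes tested there had a median of 0.22, below the bound set against it as the cause of the pattern. The quartiles across genes were -0.10 and 0.59, and 219 genes were higher and 46 lower there, so the loss stays open for part of the genes.

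Of 43 early 2-cell genes 18 were higher after Kdm3aWT than after Kdm3aHA in mDKO embryos, 1 was lower and 24 did not pass, with a list median of 0.73 (adjusted p = 1.54e-14; adjusted p = 0.206 with an estimated correlation). Those higher numbered 4 and 3 without Kdm3aHA replicates 1 and 2, 9 without Kdm3aWT replicate 1, and 3 and 2 without a filter on low TPM and with only the 4 libraries compared. Scaling of TPM is argued against, as the list kept 117% of its median under size-factor scaling, at 0.85. More Kdm3a RNA in Kdm3aWT libraries cannot be told apart, as the sign turns with 1 library. Kdm3a stood at -0.36 ± 0.23, and at -0.78 and 0.05 without Kdm3aWT replicates 1 and 2. A difference in the activity or level of the protein that the constructs make stays open and may account for the change, as does a difference between the pools of embryos, and neither was tested.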

How the results depend on the processing

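The alternatives with mDKO Kdm3aHA or control mCherry in place of mDKO mCherry libraries, and gene lists without single libraries or with other libraries in the fit, were chosen only after the data were seen. Of the counts of calls, 63 values stayed within 1.5 times the count reported and 42 did not. For gene lists, 1778 values kept their side of the threshold, 62 lost it, 41 gained it and 10, past it in at least 1 of the fits compared, changed the direction of the test; 39, 24 and 6 of these changes came from leaving out 1 library. Of the 1778, 169 did not keep the sign of the median relative to all genes, 108 of them without 1 library. For named genes 5812 kept their side of the threshold, 158 of these, not past it, with another sign, 824 lost it, 552 of them without 1 library, 58 gained it and 42 changed direction. For stage sets 61 kept their side, 7 of these with another sign of the median, 6 lost the threshold and 2 gained it. TPM keeps no depth, so what depth limits is unknown. In simulated data the changed genes were drawn only from those of higher TPM. A log2 change of 1 was recovered in 83% or more of these in the MII, E2C, L2C and injected E2C contrasts. For the stage difference it was recovered in 42%, and in 4C embryos in 7% to 11%.

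Without a filter on low TPM, which adds genes to the adjustment, the calls numbered 145 at MII, 409 at E2C and 26 for Kdm3aWT over Kdm3aHA. With all 12 uninjected libraries in 1 fit MII had 734 calls. With only the 4 libraries compared there were 10 for Kdm3aWT over Kdm3aHA at E2C, and at 4C 1 for Kdm3aWT over mCherry and 8 for Kdm3aHA over mCherry; the fit then estimates the spread from fewer libraries. A pseudocount of 0.1 gave 2 calls for Kdm3aWT over mCherry at 4C. Size-factor scaling gave 841 for Kdm3aWT over mCherry and 211 for Kdm3aWT over Kdm3aHA at E2C, and a median of 0.070 relative to all genes for E2C-lower genes with Kdm3aWT (adjusted p = 0.058); the cause was not tested. With the replicate block there were 2143 calls at MII, 2560 at E2C, and at 4C 26 for Kdm3aWT over mCherry, where Kdm3a passed (adjusted p = 0.0322, with 0.0223 to 0.999 over its alternatives), 2 for Kdm3aHA over mCherry, where Kdm3a passed as well (adjusted p = 0.0430, with 0.0430 to 1 over its alternatives), and 14 for Kdm3aWT over Kdm3aHA. At MII the block gave 24 oocyte genes higher and 8 lower, and the cumulus list passed with 1 member higher (adjusted p = 0.0286, with 5.09e-05 to 0.863 over its alternatives). The labels share only a replicate number: the deviations of same-numbered libraries had an r of 0.359 at MII, -0.019 at E2C, 0.050 at L2C and 0.177 for 4C Kdm3aWT over mCherry, and between -0.097 and 0.065 in the other injected contrasts.

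Leaving out 1 library, the lone library left in a group being assumed to vary like the others, gave 42 to 300 calls at MII, 282 to 3214 at E2C, 3872 to 4514 at L2C and 3117 to 4026 for injected mDKO over control. It gave 91 to 1551 for Kdm3aWT and 216 to 882 for Kdm3aHA over mCherry, 8 to 1493 between them, 0 to 491, 0 to 21 and 0 to 23 in the 4C contrasts, and 2575 to 3425 for the stage difference. E2C-higher genes between Kdm3aWT and Kdm3aHA had medians of -0.16 to -0.062 relative to all genes, with the call lost in 2 of the 4 cases. Lists past the threshold with or without 1 library whose test then changed direction, with the lowest and highest median relative to all genes when 1 library was left out, were in 4C embryos: Obox genes with Kdm3aWT (-0.92 to 0.67) and Kdm3aHA (-0.73 to 0.38) over mCherry, early 2-cell genes with Kdm3aHA (-0.42 to 0.72), and ribosomal protein (-0.34 to 0.089) and oocyte genes (0.098 to 0.66) between the constructs.

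With Kdm3aHA in place of mDKO mCherry libraries, ribosomal proteins stood at -0.25 relative to all genes, and Kdm3a was at 10.39, which is the injected RNA. Genes that changed direction were Lgals1 at -0.43, Ifitm2 at -0.61, S100a6 at -0.48, Spp1 at -0.56, Rps19 at -0.95, Srsf2 at -0.65, Gnas at -0.049, Sgce at -0.27, Xbp1 at -0.056, Tnfaip6 at -1.03 and Lyz2 at -0.75, while Hsd3b1, Inha and Prm1 were at 0. With control mCherry in place of mDKO mCherry libraries the reference is intact embryos, so a change of sign compares with another group. There Kdm3aWT gave 5107 calls, 547 of them shared in direction and 153 opposite. Relative to all genes, E2C-lower genes stood at -0.94, E2C-higher at 0.85, early 2-cell at -0.97, germline at -0.47 and cumulus markers at 0.20. Genes were Zscan4a at -1.94, Zscan4b at -1.53, Zscan4c at -1.51, Zscan4d at -1.57, Zscan4f at -2.02, Usp17lb at -1.12, Zfp54 at -0.63, Pramef25 at -0.54, Gm13078 at -0.77, Obox3 at -1.09, Dppa5a at -0.24, Cd52 at 2.05, Lgals1 at 0.84, Spp1 at 0.47, Hsd3b1 at 2.02, S100a10 at 0.090, Nop58 at 0.019, Psmb5 at 0.25, Cpeb1 at 0.69, Gnas at 0.51, Bax at 0.38, Isg20 at 0.17, Xbp1 at 0.13, Inhba at 0.069 and Hsd17b1 at 0.074, with Inha and Prm1 at 0.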

Other observations

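The test of E2C-lower genes in oocytes in this part and the cumulus list without single libraries were chosen only after the results were seen.

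Pluripotency and early lineage genes were lower in part at L2C, with 12 of 24 falling and 2 rising, 12 and 3 when adjusted over the list alone (adjusted p = 0.23; adjusted p = 0.0233 in fry). Prdm14, a regulator of pluripotency and germ cell fate, fell by 2.50 ± 0.25, Dppa5a by 2.18 ± 0.15 and the growth factor gene Fgf4 by 1.86 ± 0.19. Imprinted genes had 9 of 24 members lower and 3 higher at L2C, 9 and 5 when adjusted over the list alone (adjusted p = 0.452). Phlda2, a maternally expressed regulator of placental growth, was lower in mDKO at each stage without injection, at -2.02 ± 0.26 at MII, -2.37 ± 0.17 at E2C and -1.87 ± 0.13 at L2C, and Gnas rose by 1.74 ± 0.17 at L2C. The p53 target list had 4 of 15 members lower and 0 higher at L2C, in the same numbers when adjusted over the list alone, with the cell cycle inhibitor gene Cdkn1a at -1.22 ± 0.19; its median was 0.01, its mean -0.23 and its test downward (adjusted p = 0.452). Heat shock and unfolded protein genes had 4 of 21 higher and 8 lower, in the same numbers when adjusted over the list alone, with the stress factor gene Ddit3 at 1.79 ± 0.18 and the chaperone gene Hspa5 at -1.23 ± 0.15 (adjusted p = 0.297). Maternal mRNA clearance genes had 8 of 25 higher and 4 lower, in the same numbers when adjusted over the list alone (adjusted p = 0.434). Interferon response genes had 2 of 11 higher and 2 lower, in the same numbers when adjusted over the list alone, with the RNA sensor gene Ddx58 at 1.63 ± 0.21 and Isg20 at -1.51 ± 0.28 (adjusted p = 0.959).

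In MII oocytes limma made 0 calls among 15 tested cumulus and granulosa markers, while 2657 of all genes had an unadjusted p under 0.05; the list's median was 0.29, which is 0.34 above that of all genes (adjusted p = 0.264), and it passed without control replicate 2 (adjusted p = 5.09e-05) and without mDKO replicate 1 (adjusted p = 0.00543), over a range of 5.09e-05 to 0.863. Its direction rested on single libraries: relative to all genes it stood at -0.13 without control replicate 1 and at 0.11 without mDKO replicate 2, and at 0.91 and 0.69 in the cases that passed. At E2C 2 of 4 tested cumulus markers were higher, 2 of 4 sperm and spermatid markers lower and 1 of 2 blood cell markers lower in mDKO embryos. Sperm and spermatid markers at L2C had 0 of 7 members higher and 2 lower, in the same numbers when adjusted over the list alone, with a median of 0.25, a mean of -0.11 and a test downward (adjusted p = 0.959), the protamine gene Prm2 at -0.94 ± 0.23. Of 4 tested blood cell markers 2 were lower in mDKO at L2C, with the globin gene Hba-a1 at -3.00 ± 0.24, and at E2C Hba-a1 was at -3.38 ± 0.38. No mitochondrially encoded gene was in the tables, so that 0 members of that list were tested.

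A hypothesis is that part of the genes lower at E2C in mDKO embryos were already lower in the oocyte. Of the 663 E2C-lower genes 55.2% had a mean control TPM of 1 or more at MII, and the median log2 fold change of these genes at MII was -0.69, with quartiles of -1.33 and -0.23. Among 353 tested at MII, 101 were lower and 1 higher. The median lies between the bounds set for either answer, so that inheritance from the oocyte may account for part of the change and cannot be told apart from a change after fertilisation.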
